A study of Arabidopsis thaliana with 18 samples.

How the data were processed

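DNA methylation was measured by bisulfite sequencing of genomic DNA from aerial rosette tissue of Arabidopsis thaliana, harvested 21 to 22 days after sowing from plants kept in 16 h of light and 8 h of dark. The 18 libraries came from 9 lines with 2 libraries each: the wild type Columbia (Col-wt), the epigenetic recombinant inbred lines (epiRILs) 92, 150, 193 and 232, and an epiHybrid named after each of these epiRILs. About 5000 ng of DNA per sample entered bisulfite treatment, per the labels' protocols. The labels do not say whether the 2 libraries of a line came from separate plants.

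The authors' table gives, for each line, a methylation level as a fraction from 0 to 1 and the number of cytosines behind it, in windows of 100 bp placed every 50 bp across 3 intervals that the file headers mark as quantitative trait loci. The submitters' processing notes name cutadapt, BS-Seeker2, Bowtie2 and the genome build TAIR10, with no versions. The deposited table has 1 column of fractions per line, so the libraries of a line had already been combined by the authors, and how they were combined is not given in the sources used here. All cytosine contexts (CG, CHG and CHH) share 1 value. The deposited count per window is a number of cytosines, not of reads: a level is missing exactly where this count is 0. Read depth is therefore unknown, and neither intervals nor detection limits that need it are given. The table also holds mid-parent values and log2 ratios, which were not used. The deposited differences of hybrid from mid-parent value were recomputed from the level columns, with Col-wt and the epiRIL as parents, and matched within 5.6e-16.

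Pooling of contexts affects every value. CG sites are usually methylated far more densely than CHH sites, and CHH sites are the most frequent, so a window whose CG sites are fully methylated can still have a level well under 0.5. A change in 1 context cannot be separated from a change in another.

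Before the data were examined, tests per window with limma on separate libraries and contexts had been planned, with the rule that if libraries were pooled per line, no window test would be made and the 4 lines would serve as units. The pooled columns brought that rule into force, so the unit differed from the planned one. Windows are described by the size of their difference, with no p-value. Means were compared over the 4 lines with an exact two-sided sign-flip permutation test, whose smallest possible p is 1 in 8. No such test can pass a threshold of 0.05. The 4 lines share 1 Col-wt column, so their differences from Col-wt and from the mid-parent value are not independent.

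Of 43887 windows, 39236 had a level in all 9 lines, and every second one (19614 windows, not overlapping) was used. A window was counted as lower or higher in an epiRIL when its level differed from Col-wt by at least 0.2, and an epiHybrid as above or below the mid-parent value when it differed from the mean of Col-wt and its epiRIL by at least 0.1. These limits were taken from the planned ones after the pooling of contexts was known. That Col-wt was the other parent of the hybrids is not in the labels. It is known from the published study, and the deposited differences match it. The position of a hybrid between its parents was the sum of epiHybrid minus Col-wt over the sum of epiRIL minus Col-wt, which is 0 at the Col-wt level, 0.5 at the mid-parent level and 1 at the epiRIL level. The planned position was a median over windows, with windows picked in 1 replicate and measured in the other. Here windows were picked by the mean difference of their neighbours on both sides (at least 0.2 lower in the epiRIL) and measured themselves. The standard error is a jackknife over blocks of 50 kb and measures spread along the chromosome, not between plants.

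Windows at 0.2 or more in Col-wt were called methylated. Runs of at least 5 such windows no more than 100 bp apart were called tracts. A tract was called lost in an epiRIL under 25% of the Col-wt level, kept at 75% or more, and partly methylated between these. Weakly methylated windows had a mean under 0.02 over the 9 lines. The tract, weak-window and neighbour rules were made after first values had been seen. For the named regions, a rule fixed before the data were examined joined windows of 1 direction within 100 bp and took the 3 regions with the most windows per line, comparison and direction. It had been written for CG windows and was applied to windows of all contexts.

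Genes were taken by position from the RefSeq annotation of assembly TAIR10.1. As a check on the match of coordinates, the gene annotation was shifted in steps of 250 bp: its correlation with the number of cytosines across windows was largest without a shift (0.309), against 0.275 and 0.269 at 1 step either way. Windows are neighbours and not independent replicates. Strand, exons and transposable elements were not used here, so transposable elements within a gene class, pseudogenes included, were not told apart. A window was assigned to the gene class that covered at least 50% of it. Where no class did, it was counted as having no gene, although a gene may overlap part of it. Of 65 genes in 5 lists fixed beforehand, all 65 matched the annotation and 0 lay in the intervals.

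The position measure was tested on simulated data, with 100 simulated lines over 19614 windows per setting and the losses of epiRIL 232. A true position of 0.3 returned 0.303 on average and a true position of 0.5 returned 0.508. Picking each window by its own difference returned 0.331 and 0.523. Noise was taken from the difference between epiHybrid 92 and epiRIL 92 on chromosome 3. In a first version, noise was set by the Col-wt-like level in every line, which overstated the position. It was then set by each simulated line's own level. Unchanged lines against 1 shared Col-wt were simulated with the same noise, which does not depend on the number of cytosines and so can be too small for Col-wt. Every window kept its level in these lines, so the smaller noise of lost windows was not represented. The noise SD was 0.0254 at levels from 0.02 to 0.1, against 0.0491 from 0.2 to 0.4.

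Alternatives changed the limits, the overlap of windows, the lines that needed a level, a minimum level and the size of difference for the position. Added after the data were seen were a minimum of 10 cytosines, another wild-type level, other picking of windows, subtraction of background and leaving out each line. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.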

Results

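Methylation levels were available for 9 Arabidopsis lines in 3 intervals, at 8937051 to 9698100 and 22235451 to 23207500 on chromosome 3 and at 11363351 to 11824750 on chromosome 4 (TAIR10). EpiRILs are inbred lines with nearly the same DNA sequence that carry stretches of chromosome from a parent with reduced DNA methylation; in the population these lines are known from, that parent was a mutant of DDM1, a chromatin remodeller needed for methylation of transposons. An epiHybrid is the first-generation cross of such a line, here with Col-wt. Each line had 2 libraries, combined by the authors into 1 value per window, so no value below has a replicate error. The median number of cytosines per window was 29 in Col-wt and 31 to 34 in the other lines, out of at most 72. Col-wt had the most windows with no cytosine (3488 of 43887), against 1252 in epiRIL 92. Read depth is unknown.

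The first comparison asked how far each epiRIL departed from wild type. The mean methylation level was lower in all 4 epiRILs. In epiRILs 150, 193 and 232 the loss included long tracts, most of them over annotated pseudogenes. Which of these pseudogenes are transposable elements was not examined. EpiRIL 92 had lost no tract, and 64.1% of its lower windows had no annotated gene. In the 1322 windows methylated in Col-wt, whose mean level was 0.340, epiRIL 92 held 91.4% of the Col-wt level, epiRIL 150 66.3%, epiRIL 193 60.7% and epiRIL 232 48.2%. Over all 19614 windows the mean level was 0.0405 in Col-wt and 0.0372, 0.0300, 0.0288 and 0.0253 in epiRILs 92, 150, 193 and 232. The mean difference over the lines was -0.0102 ± 0.00497 (SD, n = 4 lines), with 4 of 4 lines below Col-wt, and the exact sign-flip test gave the smallest p that 4 lines allow (1 in 8). Of the 21 tests made over lines, alternatives aside, 15 reached that value, which is above 0.05. Col-wt also read higher in weakly methylated windows (0.00790, against 0.00467 to 0.00566 in the other lines), and with this background subtracted per line the mean difference was -0.00743 and that of epiRIL 92 alone -0.00044, against -0.0033 without it.

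The intervals differed between lines. In the chromosome 3 interval that starts at 22235451, epiRILs 150, 193 and 232 held 39.9, 39.1 and 33.4% of the Col-wt level in Col-wt methylated windows, whereas epiRIL 92 held 94.9%. In the interval that starts at 8937051 the values were 99.6% in epiRIL 92, 72.2% in epiRIL 150, 80.2% in epiRIL 193 and 40.4% in epiRIL 232. On chromosome 4, epiRILs 150 and 232 stood at 104.3 and 98.0%, and epiRILs 92 and 193 at 62.9 and 53.8%. Apart from a screen for a single line far from the others, given below, these differences between lines were not tested.

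By windows, 103, 447, 514 and 654 were lower by at least 0.2 in epiRILs 92, 150, 193 and 232, and 41, 42, 32 and 38 were higher. With at least 10 cytosines in the 3 lines compared, 63, 395, 458 and 594 windows were lower and 23, 19, 11 and 26 higher. Simulated unchanged lines gave 16.1 lower and 16.0 higher on average over all windows. Their noise was that between the columns of line 92, in which 6.14 and 12.7% of windows had under 10 cytosines, against 17.7% in Col-wt, so it can understate the noise of comparisons with Col-wt. A window can be lower by this limit only where Col-wt is methylated. Pseudogenes covered 5.88% of all windows but 43.1% of the Col-wt methylated ones, and held 20.4, 49.9, 57.6 and 57.8% of the lower windows in epiRILs 92, 150, 193 and 232. Windows with no gene were 37.9% of the methylated ones and held 64.1, 37.1, 35.2 and 33.9% of the lower windows. Protein-coding genes covered 16.0% of the methylated windows and held 9.71, 9.17, 4.09 and 5.81%. Of the methylated windows over pseudogenes, 3.68, 39.1, 51.9 and 66.3% were lower in the 4 lines, against 13.2, 33.1, 36.1 and 44.3% of those with no gene. These shares were not tested. Of 53 measured pseudogenes, 21 had at least 5 Col-wt methylated windows. At least 5 lower windows were found in 12 pseudogenes in epiRIL 150, 12 in epiRIL 193 and 16 in epiRIL 232, against 2 in epiRIL 92. Of 605 protein-coding genes, 8 had at least 5 Col-wt methylated windows, and 1 to 3 per line had at least 5 lower ones.

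The longest lost region was the same in epiRILs 150, 193 and 232. It spans 23108851 to 23115850 on chromosome 3 and overlaps the pseudogenes AT3G62475, AT3G62480 and AT3G62490. Across its 70 windows the level was 0.457 in Col-wt and 0.0137, 0.0209 and 0.0284 in the 3 epiRILs. A second region at 22235451 to 22242050, over AT3G60164, AT3G60170 and AT3G60176, read 0.369 in Col-wt and 0.0143 in epiRIL 150, and up to position 22241250 it read 0.367 in Col-wt and 0.0139 in epiRIL 193. Another, at 23203551 to 23207450 over the pseudogene AT3G62725, read 0.340 in Col-wt and 0.00990 in epiRIL 150. In epiRIL 232, the region at 9692251 to 9697850 over AT3G26483 and AT3G26486 read 0.356 in Col-wt and 0.0116 in the epiRIL, and the one at 9617851 to 9623950 over AT3G26260 and AT3G26265 read 0.298 and 0.0111. On chromosome 4, 11363451 to 11369450, over the pseudogene AT4G21360 and the microRNA gene MIR4239, read 0.307 in Col-wt and 0.00910 in epiRIL 193.

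In epiRIL 92 the regions with the most lower windows were shorter and less fully depleted. On chromosome 4 at 11680651 to 11681350, over the pseudogene AT4G22040, the level was 0.402 in Col-wt and 0.123 in the epiRIL. At 11368651 to 11369350, over MIR4239, the levels were 0.358 and 0.164, and at 11677251 to 11677750, again over AT4G22040, 0.374 and 0.163.

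Regions of higher level in an epiRIL were few and mostly of 1 window (28 of 33 regions in epiRIL 92, 26 of 34 in epiRIL 150, 25 of 28 in epiRIL 193 and 18 of 25 in epiRIL 232). The longest was in epiRIL 232 at 11818851 to 11819750 on chromosome 4, overlapping the protein-coding gene AT4G22410. There 7 of 9 windows were at least 0.2 higher (0.0111 in Col-wt and 0.259 in the epiRIL). Near LHCA2, which encodes a light-harvesting protein of photosystem I, the windows at 22747851 to 22748450 on chromosome 3 read 0.0872 in Col-wt and 0.381 in epiRIL 92. The first 3 of these windows read 0.117 in Col-wt and 0.346 in epiRIL 193. A region of 2 windows past the limit lay near ARP7, an actin-related protein gene (0.0510 in Col-wt, 0.292 in epiRIL 92), and one near CYP71B23, a cytochrome P450 gene (0.457 in Col-wt, 0.799 in epiRIL 150). The regions near ARABIDILLO-2 and AT3G26240 rested on medians of 2.5 and 3 cytosines in the least covered line.

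Grouped into 52 tracts methylated in Col-wt, 0 were lost in epiRIL 92, 14 in epiRIL 150, 11 in epiRIL 193 and 19 in epiRIL 232. In all, 22 different tracts were lost in at least 1 line and 6 of them in epiRILs 150, 193 and 232 together. Of the 22, 18 overlapped a pseudogene, against 26 of all 52. The 14 tracts kept in all 4 lines included one over GATA4, which encodes a GATA-type transcription factor, and one within 1000 bp of ATCES1, a ceramidase gene. EpiRILs 150 and 232 shared 399 lower windows, epiRILs 193 and 232 shared 369 and epiRILs 150 and 193 shared 269, where independent lists drawn from the Col-wt methylated windows would share 221.1, 254.3 and 173.8. EpiRIL 92 shared 45, 66 and 61 with epiRILs 150, 193 and 232, each above the value for such lists (34.8 to 51.0). Independent lists from all windows would share 2.3 to 17.1, and simulated unchanged lines with a shared Col-wt gave 4.1. Part of the excess may come from the shared Col-wt. Col-wt alone stood at least 0.2 above all other lines in 22 windows, against 2 to 5 windows for any other line. Such windows count as lower in every epiRIL. Their median was 3.5 cytosines in Col-wt, and 5 of them had at least 10.

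**Figure D1:**
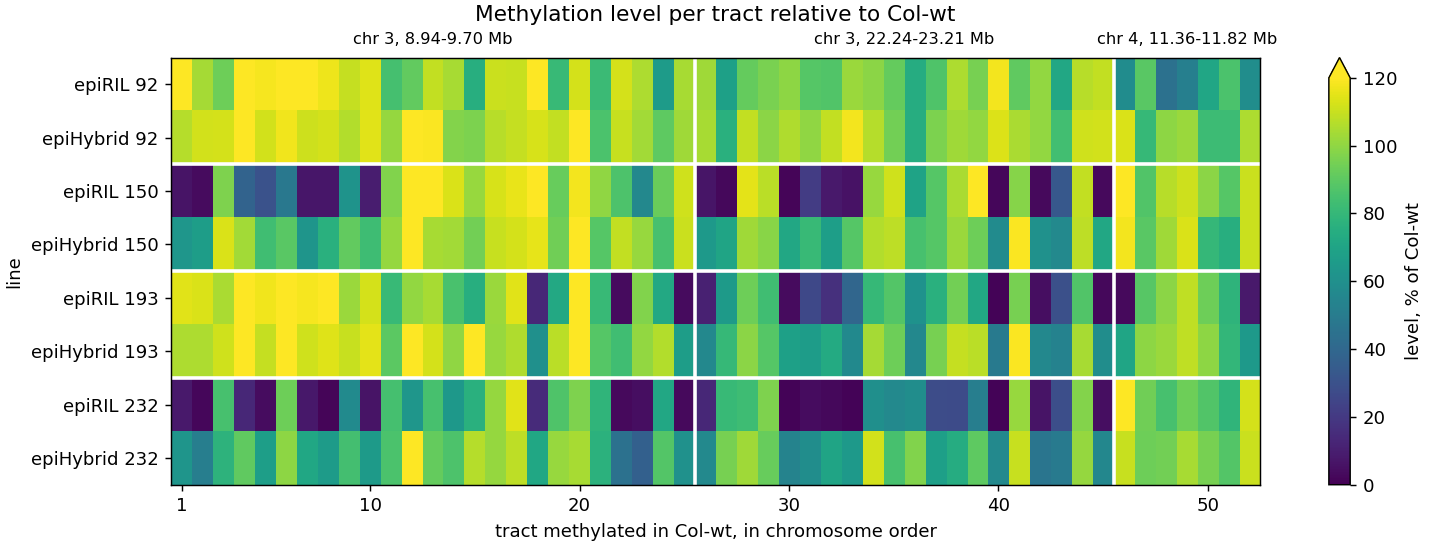
Level of each of the 52 tracts (columns, in chromosome order within the 3 intervals) in each epiRIL and epiHybrid (rows), as a percent of the Col-wt level, by colour. Dark cells in the rows of epiRILs 150, 193 and 232 are the 14, 11 and 19 lost tracts, and the row of epiRIL 92 has 0.

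The second comparison set the epiHybrids between their parents. In Col-wt methylated windows, epiHybrid 92 held 100% of the Col-wt level, epiHybrid 150 89.4%, epiHybrid 193 85.2% and epiHybrid 232 74.5%, each above its epiRIL. Over all windows the epiHybrids were lower than Col-wt in 4 of 4 lines, by a mean difference of -0.00466 ± 0.00275 (SD, n = 4 lines), and higher than their epiRILs in 4 of 4 lines, by 0.00549 ± 0.00233 (SD, n = 4 lines). With background subtracted per line, the difference from Col-wt was -0.00219, with 3 of 4 lines below Col-wt and epiHybrid 92 at 0.00141 (exact sign-flip p = 0.25). Windows at least 0.2 lower than Col-wt numbered 52, 90, 128 and 221 in epiHybrids 92, 150, 193 and 232, and 14, 57, 90 and 181 with at least 10 cytosines. In the largest lost region, over AT3G62475 to AT3G62490, epiHybrids 150, 193 and 232 read 0.277, 0.257 and 0.214, between 0.457 in Col-wt and at most 0.0284 in the epiRILs. In the gained region that overlaps AT4G22410, epiHybrid 232 read 0.0964.

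The third comparison asked whether the epiHybrids had the mid-parent level. Averaged over all windows they lay close to it: the difference was 0.000411 ± 0.00058 (SD, n = 4 lines), above 0 in 3 of 4 lines (exact sign-flip p = 0.25). Its size depended on the setting: with background subtracted per line it was 0.00153, at the smallest p possible, and it was 0.000165 without line 150 and 0.000636 without line 232. In Col-wt methylated windows it was 0.0135 ± 0.00863 (SD, n = 4 lines), above 0 in 4 of 4 lines, at the smallest p possible. The difference there was 0.0147 in line 92, 0.0213 in line 150, 0.0166 in line 193 and 0.00122 in line 232.

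Where the epiRIL had lost methylation, the epiHybrids of lines 150 and 193 lay nearer to Col-wt than to the epiRIL. The position was 0.315 ± 0.0454 (block SE) in 379 windows of line 150 and 0.397 ± 0.0352 in 431 windows of line 193, where 0.5 is the mid-parent level. In line 232 it was 0.482 ± 0.0423 in 601 windows, within its error of 0.5. In line 92 it was 0.126 ± 0.0930 in 43 windows, but 0.515 ± 0.115 in the 103 windows picked by their own difference, so its direction depends on how windows were picked. The hybrid was above the mid-parent value by 0.0408 ± 0.0277 (SD, n = 4 lines) in the windows picked by their neighbours, in 4 of 4 lines and at the smallest p possible. In windows picked by their own difference it was 0.0158, above in 2 of 4 lines (exact sign-flip p = 0.5). With a difference 1.5 times as large, or with another wild-type level, it was above in 3 of 4 lines (exact sign-flip p = 0.25).

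The lost tracts regroup the same levels and are no separate support. Among them the same order held. EpiHybrid 150 had a median of 68.7% of the Col-wt level in its 14 lost tracts (range 58.0 to 88.5%), with a median mid-parent value of 53.1%, and 14 of 14 were above their mid-parent value. EpiHybrid 193 had 65.0% in 11 tracts, of which 10 were above, and epiHybrid 232 had 60.8% in 19 tracts, of which 16 were above. The 3 of line 232 that were not above held 80, 38 and 70 windows, with positions of 0.660, 0.571 and 0.568. The tract of 80 windows, over AT3G26260 and AT3G26265, stood at 36.8% of Col-wt in epiHybrid 232. These tracts weigh heavily in the pooled position of line 232 (0.482), which therefore does not describe most of its lost tracts. In tracts kept by the epiRIL, the median level of epiHybrids 92, 150, 193 and 232 was 107.3, 104.2, 105.4 and 100.4% of Col-wt.

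**Figure D2:**
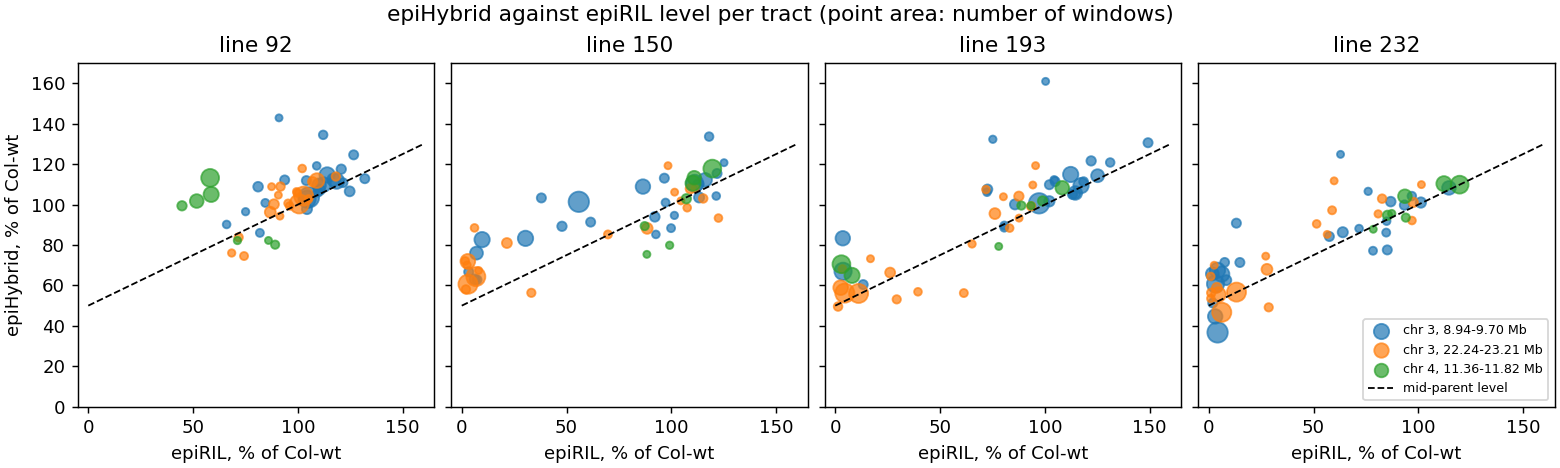
Level of each tract in the epiHybrid (vertical axis) against its epiRIL (horizontal axis), both as a percent of Col-wt, for the 4 lines; point area grows with the number of windows, colours are the 3 intervals and the dashed line is the mid-parent level. All 14 lost tracts of line 150, 10 of 11 of line 193 and 16 of 19 of line 232 lie above the line.

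Departures of at least 0.1 from the mid-parent value were found above it in 193, 212, 213 and 159 windows and below it in 79, 77, 78 and 92 windows of lines 92, 150, 193 and 232. Simulated unchanged lines gave 92.9 above (at most 116) and 91.2 below (at most 120). They hold no lost windows, where noise was smaller, so these counts can be too high for lines whose epiRIL lost methylation. The share above was 71.0, 73.4, 73.2 and 63.3% of departures. With another wild-type level, averaged over Col-wt and the epiRILs that had kept the window, it was 62.4, 68.7, 67.5 and 54.1%. With at least 10 cytosines it was 82.1, 81.1, 83.7 and 67.1%, from 138, 159, 154 and 114 windows above and 30, 37, 30 and 56 below. Pairs of lines shared 27 to 43 windows above and 25 to 33 below, against 14.8 and 15.0 for simulated unchanged lines and 0.3 to 2.3 for independent lists, and part of this excess may come from the shared Col-wt.

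In line 92 the longest regions above the mid-parent value were on chromosome 4. At 11367251 to 11368150, over AT4G21360, epiHybrid 92 read 0.385, Col-wt 0.320 and epiRIL 92 0.190. EpiRILs 150 and 232 and their epiHybrids also read above Col-wt in each window of this region. A pair of further regions lay over AT4G22040: at 11680551 to 11681350 the hybrid read 0.439 with a mid-parent value of 0.262, and at 11676451 to 11677350 it read 0.496 with a mid-parent value of 0.344. In 4 tracts of this interval (148 windows), the mean level was 0.332 in Col-wt, 0.183 in epiRIL 92 and 0.354 in epiHybrid 92, with SDs over windows of 0.0890, 0.0580 and 0.0870. These tracts were singled out after their values were seen. In most of their windows epiRIL 150, which kept these tracts, and epiHybrid 150 also read above Col-wt. The other partly methylated tract of this interval in line 92 had 82.2% of the Col-wt level in the hybrid, under its mid-parent value of 85.6%. In the interval that starts at 22235451, 0 of 3 such tracts were above the mid-parent value, and over all intervals 5 of the 9 partly methylated tracts of line 92 were above. In lines 150, 193 and 232 it was 6 of 7, 4 of 8 and 10 of 11. Of the 4 chromosome 4 tracts named for line 92, those over AT4G21360 and over AT4G22410 with AT4G22415 were lost in epiRIL 193.

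**Figure D3:**
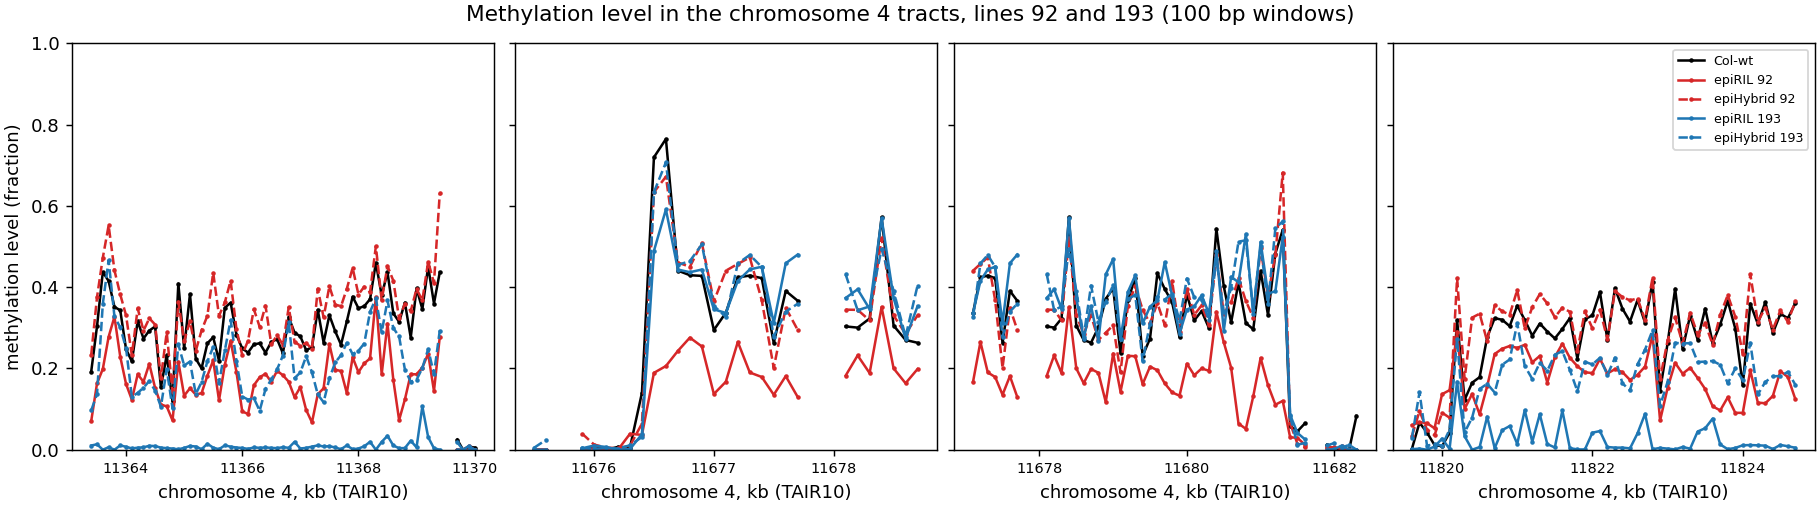
Methylation level (fraction, vertical axis) along 4 tracts of chromosome 4 (horizontal axis, kb) in 100 bp windows, for Col-wt, epiRILs 92 and 193 (solid) and epiHybrids 92 and 193 (dashed); gaps are windows without a level in all lines, and neighbouring panels can show some of the same windows. EpiRIL 92 averages 0.183 over the tracts, against 0.332 in Col-wt and 0.354 in epiHybrid 92.

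In line 150 the longest region above the mid-parent value, at 9618551 to 9620350 on chromosome 3, lay within 1000 bp of the pseudogene AT3G26260. Over its 18 windows epiRIL 150 read 0.0506 and epiHybrid 150 0.314, above Col-wt at 0.272. Col-wt also lay under the other lines that kept this region, with 0.273 and 0.295 in epiRILs 92 and 193. EpiHybrids 92 and 193 read 0.301 and 0.303 there. A second region, at 9236751 to 9237650 over AT3G25485, read 0.0190 in the epiRIL and 0.281 in the hybrid, with 0.261 in Col-wt. The tract at 9236851 to 9241150 stood at 114.0 and 112.3% of Col-wt in epiRILs 92 and 193. In line 193, 9615951 to 9617150 over AT3G26260 read 0.00700 in the epiRIL and 0.279 in the hybrid, with 0.294 in Col-wt, and 11363551 to 11364050 near AT4G21360 read 0.00480 and 0.341, with 0.359 in Col-wt. In line 232, 22389851 to 22390450 over AT3G60565 read 0.00470 and 0.255, with 0.253 in Col-wt.

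**Figure D4:**
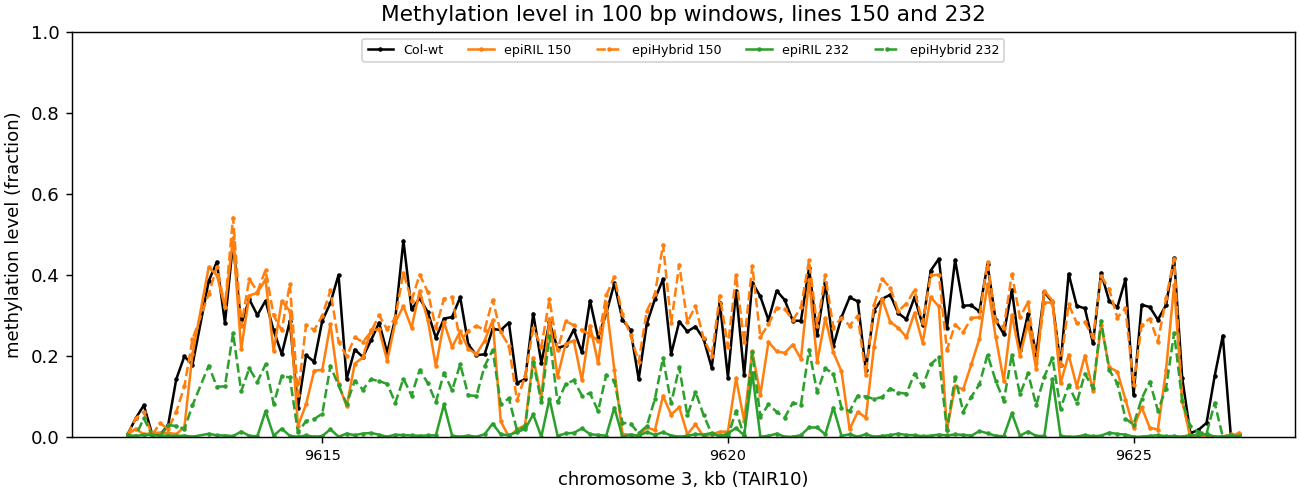
Methylation level (fraction, vertical axis) in 100 bp windows along chromosome 3 (horizontal axis, kb) around 9618551 to 9620350, for Col-wt, epiRILs 150 and 232 (solid) and epiHybrids 150 and 232 (dashed). In that region epiHybrid 150 averages 0.314 while epiRIL 150 averages 0.0506; epiHybrid 232 averages 0.0714.

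Most regions below the mid-parent value held 1 window past the limit (64 of 71 in line 92, 47 of 60 in line 150, 60 of 68 in line 193 and 61 of 73 in line 232), and none held more than 4. In line 193, the region at 11526451 to 11526750 on chromosome 4 near GA3OX3, a gibberellin 3-oxidase gene, read 0 in epiHybrid 193, 0.0174 in epiRIL 193 and 0.234 in Col-wt. In line 232, 9471151 to 9471450 on chromosome 3 near NIMIN-2, whose product binds the defence regulator NPR1, read 0.0143 in the hybrid, 0.00260 in the epiRIL and 0.731 in Col-wt. In line 92, 9595551 to 9595750 near CYP71B3 read 0.455 in the hybrid against 0.654 in Col-wt and 0.662 in the epiRIL. In line 150, 11756951 to 11757350 near AT4G07055 read 0.465 in the hybrid, with a mid-parent value of 0.647.

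Of the lists fixed beforehand, 0 of 14 loci known to respond to loss of methylation, 0 of 18 genes of the methylation machinery, 0 of 15 flowering and light genes, 0 of 9 clock genes and 0 of 9 growth genes lay in the 3 intervals, so none was measured here.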

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

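Tests for the epiRIL 92 levels were chosen only after the values they measure had been seen. Among 33 quantities examined over the 4 lines, 5 had 1 line far from the other 3; chance alone gives about 1 in 20.

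EpiRIL 92 stood apart in the chromosome 3 interval that starts at 22235451 in 3 related values. Its mean level there was 0.0320, against 0.0185 to 0.0204 in the other epiRILs, it held 94.9% of the Col-wt level in Col-wt methylated windows, and 30 windows were lower than Col-wt, against 257 to 279. EpiHybrid 232 had 92 windows below the mid-parent value over all intervals, against 77 to 79 in the other lines and 91.2 on average (at most 120) in simulated unchanged lines. EpiHybrid 193 had 35 such windows in the interval that starts at 22235451, against 28 or 29.

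The opposite case was epiRIL 92 on chromosome 4, where 4 tracts held 44.7 to 58.6% of the Col-wt level and the hybrid of the line 99.4 to 113.2%. Few cytosines are argued against, since the median was 41.5 cytosines per window in epiRIL 92. Of the windows, 85.8% lay between 25 and 75% of Col-wt, as an average of a methylated and an unmethylated plant or allele may give, but a partial loss in every cell would look alike, and the pooled column does not separate these. Wild-type DNA mixed into the epiRIL 92 libraries throughout was not settled by windows near 0. In a set of 1193 windows where Col-wt and 3 epiHybrids averaged 0.2 or more, 3 were at or under 0.02 in epiRIL 92. They met the bound of 3 set against mixing, but not by more than the square root of the count. That margin was required only after the 3 windows were seen, and without it mixing would be argued against. An added condition of the first version had been dropped before this count, and 0 of the windows lay on chromosome 4. In lost tracts, epiHybrids 150, 193 and 232 held at most 88.5, 83.3 and 90.8% of Col-wt. If only the epiRIL libraries were mixed, the hybrid would still inherit lost tracts. The 99.4 to 113.2% of epiHybrid 92 thus argues against mixing alone, provided the crossed plant was like those sequenced. A parent plant of the cross that differed from the epiRIL 92 plants sequenced is a further possibility that was not tested.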

How the results depend on the processing

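No paired analysis was possible because the columns pool the libraries of a line and carry no replicate numbers; this concerns libraries only, since the tests over lines set each epiHybrid against its own epiRIL or mid-parent value. For the same reason limma, its F test, the arcsine scale, the replicate block, array weights and leaving out libraries were not run, and the requirement of a level in the 3 lines compared was tried for counts of windows only, since a level in every line is already the main rule for the means. Alternatives on the number of cytosines, the wild-type level, picking by own difference, background and lines were chosen after seeing the data. Unknown read depth keeps noise of single windows from being separated from real differences.

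Counts are given as percent of the windows used, for lines 92, 150, 193 and 232 in that order; the main values were 0.525, 2.28, 2.62 and 3.33% lower in the epiRIL, 0.209, 0.214, 0.163 and 0.194% higher in the epiRIL, 0.984, 1.08, 1.09 and 0.811% above the mid-parent value and 0.403, 0.393, 0.398 and 0.469% below it. Using all overlapping windows, or windows with a level in the 3 lines compared, kept every count within 1.5 times. Limits of 0.4 and 0.2 gave 0.0561, 0.489, 0.4996 and 0.632% lower in the epiRIL, 0.0204, 0.0153, 0.0153 and 0.0204% higher in the epiRIL, 0.138, 0.189, 0.158 and 0.117% above the mid-parent value and 0.0357, 0.0867, 0.0459 and 0.0663% below it. Limits of 0.1 and 0.05 gave 2.01, 3.96, 4.3 and 5.33% lower in the epiRIL, 1.01, 0.964, 0.846 and 0.969% higher in the epiRIL, 2.8, 3.56, 3.08 and 2.76% above the mid-parent value and 1.54, 1.59, 1.58 and 2.04% below it. The size of the limit sets these counts by construction. Requiring a mean level of at least 0.1, still as percent of all 19614 windows, left 0.24, 0.26 and 0.26% below the mid-parent value in lines 92, 150 and 193 and 0.122% higher in epiRIL 232. At least 10 cytosines, as percent of the windows that meet this, left 0.132, 0.109 and 0.0635% higher in epiRILs 92, 150 and 193, 0.172, 0.213 and 0.173% below the mid-parent value in these lines and 0.0802% lower than Col-wt in epiHybrid 92, where the main value was 0.265%; the cause was not tested.

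Windows picked by their own difference gave a position of 0.515 in line 92, on the other side of 0.5 from 0.126; of 0.367 in line 150; and of 0.501 in line 232. The position of line 232 also crossed 0.5 with a difference 1.5 times as large (0.508) and stood at 0.5 with the other wild-type level, each within its block SE of the main value. The cause was not tested. Lines 150 and 193 stayed under 0.5 in all 5 alternatives. The 5 mean differences over lines in all or in Col-wt methylated windows kept the sign of their mean with all overlapping windows, with background subtracted and without each line in turn, where 3 lines allow no p under 0.25; epiHybrid minus Col-wt fell in size to -0.00219 with background subtracted, and 1 line changed sign. The difference from the mid-parent value in lost windows was 0.0158 with windows picked by their own difference and 0.0321 to 0.0526 without single lines, where the main value was 0.0408; background was not subtracted from it. The difference from the mid-parent value over all windows kept its sign but not its size: it was 0.00153 with background subtracted and 0.000165 to 0.000636 without single lines, where the main value was 0.000411.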

Other observations

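All tests here were chosen after the data had been seen, and those on the shared lost windows, on the other wild-type level in line 193 and on other picking of windows in line 150 after the result itself. EpiRILs 150 and 232 had lost methylation in 350 of the same windows, where the position was 0.318 ± 0.0465 (block SE) in epiHybrid 150 and 0.495 ± 0.0431 in epiHybrid 232. The other pairs lay closer, at 0.369 ± 0.0371 in epiHybrid 150 and 0.458 ± 0.0157 in epiHybrid 193 over 216 windows, and at 0.413 ± 0.0399 in epiHybrid 193 and 0.495 ± 0.0382 in epiHybrid 232 over 322 windows. The differences between hybrids were not tested.

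The position of epiHybrids 150 and 193 nearer to Col-wt in lost windows may be a technical effect if Col-wt read too low. With the other wild-type level it was 0.347 in line 150 and 0.427 in line 193, with block SEs of 0.0307 and 0.0268. That level still includes Col-wt, so a low Col-wt is corrected only in part. The position moved by a similar amount in both lines, from 0.315 and 0.397. In line 150 it stayed well under 0.5, which argues against a low Col-wt as the whole cause there. In line 193 it lay closer to 0.5, and the check does not decide, as a fuller correction could bring it nearer still. The position was 0.5 in line 232, and 0.1145 in line 92, whose direction depends on how windows were picked. Noise and the picking of windows were checked in 662 windows picked from epiRIL 92 minus epiRIL 232 alone. That choice uses neither Col-wt nor lines 150 and 193. The position there was 0.263 in epiHybrid 150 and 0.358 in epiHybrid 193, with block SEs of 0.0674 and 0.0644. Not all of these windows were lost: epiRILs 150 and 193 read 0.130 and 0.161, against 0.0294 and 0.0321 in windows picked by their neighbours. In kept tracts, epiHybrids 150 and 193 had medians of 104.2 and 105.4% of Col-wt. Kept windows with the hybrid above Col-wt lower the position, so the check does not decide. Gain of methylation on the epiRIL-derived allele in the hybrid is a candidate biological explanation, which the columns, having no alleles, do not test. A difference between the parent plants and the plants sequenced stays open as well.

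Col-wt stood above the other lines where methylation was weak. In 15675 such windows its mean level was 0.00790, against 0.00467 to 0.00566 in the other lines. Few cytosines are argued against, since the excess over the mean of the other lines was 0.00244 in the 8593 windows with at least 20 cytosines in every line. The excess was alike over protein-coding genes, pseudogenes and windows without a gene, with the largest 1.13 times the smallest, as a library-wide background such as incomplete conversion could give. A difference of the Col-wt line passed on in part to its hybrids would put each epiHybrid about midway between its parents. EpiHybrids 92, 150, 193 and 232 read 0.00524, 0.00563, 0.00525 and 0.00557, against 0.00503, 0.00566, 0.00538 and 0.00467 in their epiRILs. Each lay nearer to its epiRIL than to Col-wt, which argues against such a difference in these windows. A difference of Col-wt that hybrids do not inherit was not separable from a background. The difference of epiRILs from Col-wt over all windows includes the excess.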
